A study of Homo sapiens with 6 samples.

How the data were processed

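The series holds 6 Hi-C libraries of MCF7L and T47D cells in 3 groups of 2, named by the labels as parental MCF7L, tamoxifen-resistant MCF7L with sapitinib and tamoxifen-resistant T47D with sapitinib. The cells were fixed and digested with HindIII, per the labels' protocols. HOMER, with no version, and the genome build hg19 are named in the submitters' processing notes with no role. The callers of domains and loops, their thresholds and whether replicates were pooled are not given in the sources used here. What was analysed were the authors' comparison tables, which write MCF7, the name used here for both. These hold no value per library, so depth per library is unknown and no test across replicates was made.

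For domains, the authors deposited 4 comparisons, from parental to resistant cells and from resistant to sapitinib-treated cells in each line. Each row is a feature of the first condition (domain, gap or boundary) in steps of 40 kb, with the features it overlaps in the second condition and the authors' class: not-change, conserve-expand, conserve-shrink, fuse, split, shift, del-TAD or new-TAD. The additional class word undefined was dropped, and neo-TAD was read as new-TAD. Gaps and boundaries, 150, 126, 171 and 277 features of the 4 comparisons, were left out of shares. A domain counted as changed in any class but not-change. The direction of the tables was checked on the resistant domains. All 5632 MCF7 and 5621 T47D domains listed as second condition at the first step were among the 5694 and 5702 domains listed as first condition at the second step. The sapitinib domains were read from the second-condition cells and may miss about as many (98.9% and 98.6% of resistant domains were recovered that way).

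For loops, the authors deposited 4 lists of promoter loops with opposite changes at the 2 steps, with anchors of 40 kb and a read value per loop. That value is a score of the authors with decimals and an unstated normalization, and it is 0 where no loop was called, per the file headers and values. It was used only within a list, to describe and rank loops and, on the log2 scale with the trend over span removed, to test chromosomes against the others by 10000 permutations of loops. Column names of the deposited tables were the same for both lines, and the condition was taken from the table titles. Coordinates are hg19 as deposited, with starts written from base 1.

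Shares carry 95% Wilson intervals, which cover the counting of domains only. Differences between comparisons were tested with two-sided sign-flip permutation over 23 chromosomes (100000 resamples), recurrence and overlaps with 1000 circular shifts within chromosomes (200 draws for shared loops at other tolerances, for overlap of domains by 50% and for permuted classes in the overlap between lines), domain length with 10000 permutations of classes within chromosomes, and loop sets and gene lists with two-sided Fisher's exact tests. Chromosomes and loops are not biological replicates, so these p-values do not cover the spread between cultures. Loops counted as shared when both anchors lay within 1 bin. An anchor was placed by its midpoint. Benjamini-Hochberg adjustment was applied within each family. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

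The tests were tried on simulated classes on the 5694 resistant MCF7 domains. A planted difference of 10 points was found in 100% of 200 runs and one of 5 points in 71%, with 3% of runs below 0.05 when none was planted. A planted odds ratio of 4 was estimated at 4.01 on average. The overlap test was too liberal, with 16% of 100 runs below 0.05 when nothing was planted, so its excess is given beside the highest simulated one.

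Before the data were examined, 14 gene lists, the alternatives and the naming rule were fixed. The rule named, per loop list, up to 20 genes of the lists and the first 10 loops by the authors' score, and list genes in changed domains of both lines. A gene table of another build (GRCh38.p14) was used only for symbols and gene types. It matched 535, 490, 537 and 180 symbols of the 4 loop lists directly and 18, 19, 10 and 5 through older names. Genes could be placed only through loop anchors. The planned test of gene lists over changed domains and the alternatives that need gene positions in hg19 were not run.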

Results

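The study used chromosome conformation capture (in situ Hi-C with HindIII digestion) to follow genome folding through acquired tamoxifen resistance and its treatment with sapitinib, an inhibitor of EGFR, HER2 and HER3. It worked in MCF7L, which the comparison tables call MCF7 (the name used below), and in T47D. MCF7 and T47D are estrogen receptor positive breast cancer cell lines of luminal type. Each of 3 groups held 2 libraries: parental MCF7L, tamoxifen-resistant MCF7L given sapitinib, and tamoxifen-resistant T47D given sapitinib. The resistant cells were kept in 100 nM tamoxifen, and the labels give no sapitinib dose for the Hi-C cultures. The tables also hold resistant MCF7, parental T47D and resistant T47D cells, which have no library in this series. Each step below, from parental to resistant or from resistant to sapitinib-treated cells, uses at least 1 of these conditions, and the step from parental to resistant T47D uses no library of the series. The values analysed were the authors' comparison tables and not values per library, so no spread between replicates could be measured and the sequencing depth is unknown. Intervals and tests below treat domains, loops or chromosomes as units.

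The first comparison asked how topologically associating domains, the self-contacting blocks of a chromosome, changed as parental cells became resistant, and the second how they changed when the resistant cells received sapitinib. In MCF7, 67.7% of 5670 parental domains were placed in a class of change in resistance (95% Wilson interval 66.4 to 68.9), and 56.6% of 5694 resistant domains were so placed with sapitinib (55.3 to 57.9). In T47D the shares were 70.8% of 5683 domains (69.6 to 71.9) and 56.7% of 5702 (55.4 to 58.0). Among fusions, splits, shifts and losses, fusion with a neighbour held the most domains of the first condition at each step in both lines. Fusion took 21.1% of MCF7 and 22.8% of T47D parental domains in resistance, against 13.5% and 18.1% of resistant domains with sapitinib. A fusion counts every domain that joins and a split only the 1 that divides, so these shares do not rank the number of events. Splits took between 7.56% and 9.98% of domains and shifts between 4.25% and 7.44%. Loss of a domain was rare, with 13 and 25 domains in MCF7 and 12 and 18 in T47D. Many changes were small: domains that only expanded or shrank made up 26.3% to 30.4% of each table, and 69.6% to 79.9% of these moved neither end by more than 1 bin of 40 kb. With only fusions, splits, shifts and losses counted, an alternative chosen after seeing the data, the changed shares were 37.3% and 27.99% in MCF7 and 40.4% and 30.4% in T47D.

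**Figure D1:**
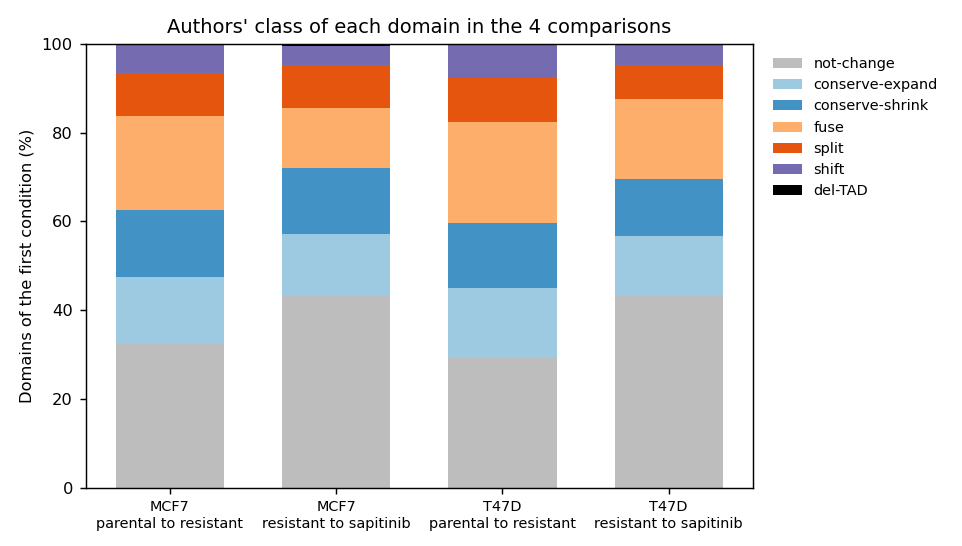
Each bar is 1 comparison and shows the percent of the first condition's domains in each of the authors' classes. The unchanged share is 32.3% and 43.4% in MCF7 and 29.2% and 43.3% in T47D.

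More domains were classed as changed on the way to resistance than with sapitinib, in both lines. Averaged over 23 chromosomes, the MCF7 share was 10.3 percentage points higher at the first step (SD over chromosomes 5.71, higher on 22 of 23 chromosomes), and the T47D share 13.1 points higher (SD 8.21, 21 of 23). Each gave an adjusted p of 2e-05 in a two-sided sign-flip permutation test over chromosomes, with Benjamini-Hochberg adjustment over 4 pairs and a raw p of 1e-05, the smallest that 100000 resamples can give. The test shows only that the difference is spread over the genome. The steps differ in which cells have libraries in this series, and how many calls differ between replicates is unknown. Between the lines, the first step changed 2.32 points more domains in T47D than in MCF7 (SD 6.71, 18 of 23 chromosomes), which did not pass the permutation test (adjusted p = 0.149). It passed when chromosomes were weighted by their domains (3.18 points, adjusted p = 0.0178) and when chromosome 17 was left out (3.14 points, adjusted p = 0.0195), in the same permutation test. The second step differed by -0.42 points between T47D and MCF7 (SD 7.88, adjusted permutation p = 0.798). Chromosome 20 of T47D went from 69.9% changed domains at the first step to 36.9% at the second.

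**Figure D2:**
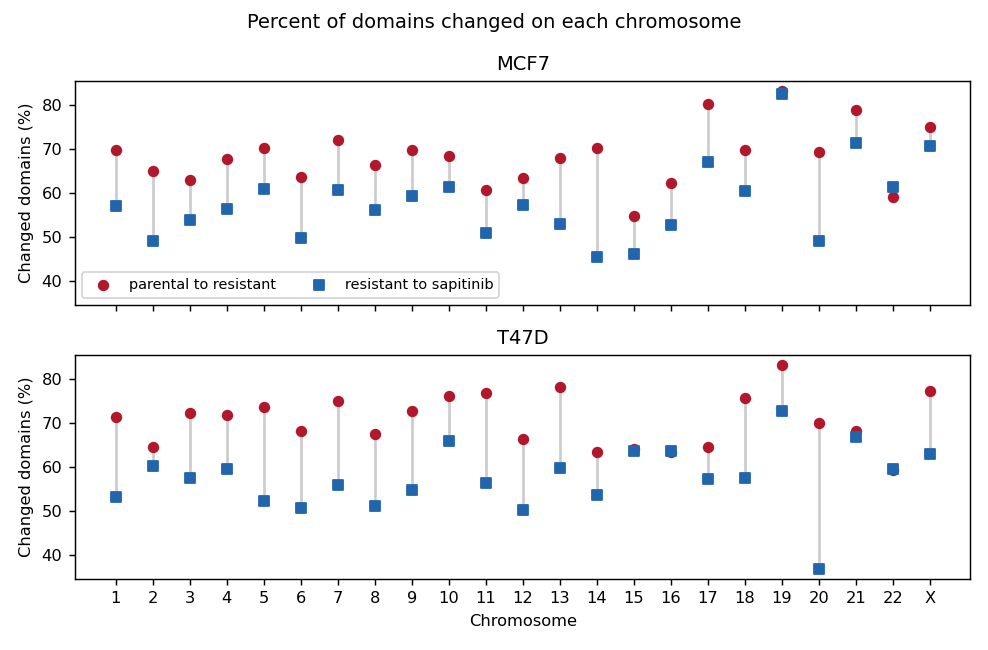
Points give the percent of domains changed on each chromosome, red circles from parental to resistant cells and blue squares from resistant to sapitinib-treated cells, with a grey line joining the pair. The circle lies above the square on 22 of 23 chromosomes in MCF7 and on 21 of 23 in T47D.

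Domains of resistant cells that were absent from parental cells changed with sapitinib more often than the others. In MCF7, 69.2% of 3860 resistant domains with no identical parental domain changed with sapitinib, against 30.0% of the 1834 that had one. The odds ratio was 5.26 (permutation p = 0.002, the smallest that 1000 circular shifts of the classes along chromosomes can give, whose median odds ratio was 1.04). In T47D the shares were 64.3% of 4041 and 38.2% of 1661, with an odds ratio of 2.92 (permutation p = 0.002, median of shifts 0.999). Looser matching to the parental domains lowered the odds ratios. With ends within 1 bin they were 3.41 in MCF7 and 2.34 in T47D, and by 50% reciprocal overlap 2.13 and 1.77 (each permutation p = 0.002). Both steps use the same resistant domain calls, which raises the odds ratio with no recurrence of change, and the shifts do not model this. With the domains of the other line's parental, resistant or sapitinib-treated cells in place of the parental ones the odds ratio was 3.77, 4.14 and 5.54 for resistant MCF7, and 4.62, 3.57 and 4.65 for resistant T47D. Among pairs of conditions, the resistant and sapitinib-treated cells of a line shared the most domains with identical ends, 2471 in MCF7 and 2468 in T47D. Parental MCF7 shared 1834 domains with resistant MCF7, 2152 with sapitinib-treated MCF7 and 1976 with parental T47D. Parental T47D shared 1661 with resistant T47D and 1498 with sapitinib-treated T47D. Parental MCF7 and parental T47D thus shared more domains than parental and resistant cells of either line. Sign-flip permutation tests over chromosomes, chosen after seeing the data, gave 2.12 points for MCF7 domains (adjusted p = 0.103) and 4.46 for T47D domains (adjusted p = 0.00764). Resistant calls that stand apart would give the same, since no resistant cells have a library in this series and depth is unknown. Parental domains were also found less often in the other line's resistant than sapitinib-treated cells (28.6% against 33.0% for MCF7 domains, 27.8% against 30.4% for T47D domains).

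**Figure D3:**
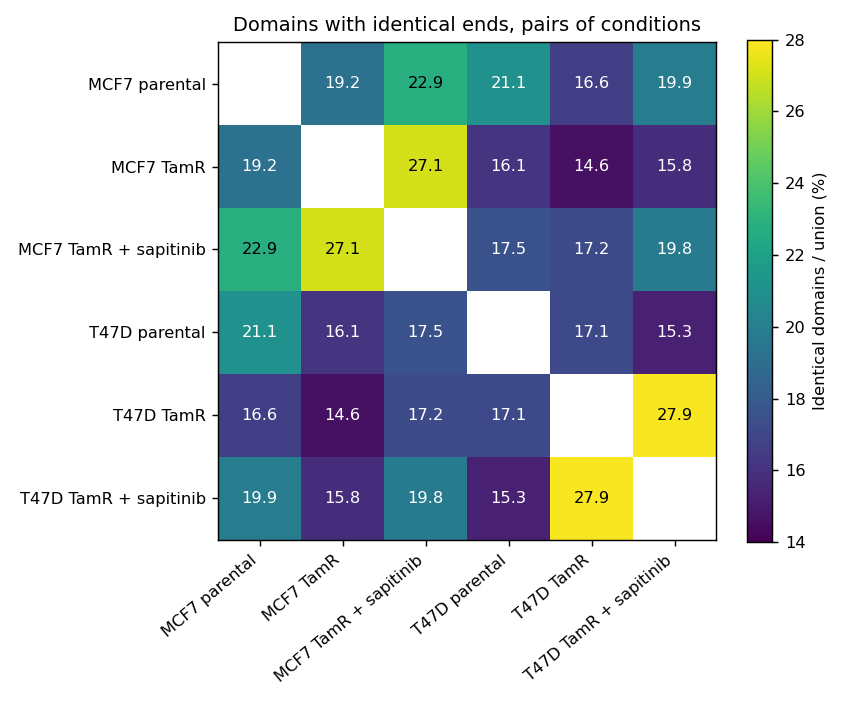
Each cell gives the domains with identical ends as a percent of the union of domains of a pair of conditions. The highest values are 27.9% and 27.1%, for resistant against sapitinib-treated T47D and MCF7.

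The same regions tended to change in both lines. Of the 1979 Mb of MCF7 domains that changed in resistance and lay in a T47D domain, 80.5% had also changed in T47D, against a mean of 75.2% under circular shifts (permutation p = 0.002, the smallest that 1000 shifts can give). With sapitinib the share was 66.8% against 61.7% (permutation p = 0.002). On simulated labels with no relation this test gave p under 0.05 in 16 of 100 runs, but the excess there never passed 2.18 points, against 5.36 and 5.09 points here. Those labels were drawn independently per domain on a single domain set, so they do not bound the excess for the real classes. For changed domains with 50% reciprocal overlap the shares were 58.8% against 56.3% by chance and 45.9% against 43.0%. With fusions, splits, shifts and losses alone they were 60.8% against 47.3% and 50.5% against 37.1%. With all classes pooled, changed domains were longer than unchanged ones. Their median was 400 kb against 360 kb at the first step in both lines (adjusted p = 9e-04, permutation of classes within chromosomes) and 440 kb against 360 kb at the second (adjusted p = 2e-04). Domains that split were the longest, with medians of 800 to 840 kb, those that shifted had 480 kb and those that shrank 400 to 440 kb. Fused domains (320 to 360 kb), expanded ones (360 kb) and lost ones (120 to 160 kb) did not exceed the unchanged ones.

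The third question was which promoter loops changed in resistance and changed back with sapitinib. The authors' lists hold 576 MCF7 and 560 T47D promoters whose loop was lost in resistance and present again with sapitinib, and 527 MCF7 and 192 T47D promoters whose loop was gained in resistance and lost with sapitinib. Each gene appears once in a list. The lost lists held 52.2% of the MCF7 and 74.5% of the T47D loops (odds ratio 0.375, p = 1.7e-22, two-sided Fisher's exact test over loops, which does not cover the spread between libraries). Their loops are said below to be lost and to come back, also where the returned loop had another anchor. Median span was 79.7 kb and 169 kb for the 2 MCF7 lists and 148 kb and 121 kb for the T47D lists. Between 22.2% and 38.0% of a list's loops spanned less than 40 kb, so that their 40 kb anchors overlapped. In the authors' deposited tables the median read score of the lost loops was 35.8 in parental MCF7 and 9.99 in parental T47D, and 40.5 and 38.0 with sapitinib. That of the gained loops was 8.37 in resistant MCF7 and 24.01 in resistant T47D, so scores were not compared between conditions. In MCF7 the parental and sapitinib-treated cells have libraries in this series and the resistant cells do not. Loss and return of a loop there cannot be told apart from a difference in library origin or depth. For 402 of the 576 MCF7 genes but 281 of the 560 T47D genes, both anchors of the returned loop lay within 1 bin of the parental one. For the other 174 and 279 genes an anchor lay elsewhere, so the lost lists join the steps by promoter. All 527 and 192 gained loops had identical coordinates at both steps. The shares of 52.2% and 74.5% thus set lists of unlike criteria against each other.

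Among the 289 genes of 14 lists fixed before the data were examined, 18 carried such a loop. GATA3 is a luminal transcription factor and partner of the estrogen receptor, and INPP4B a lipid phosphatase that dampens PI3K signalling. Both were listed with a loop lost in resistance and one present again with sapitinib, in both lines. The GATA3 promoter anchor lay on chromosome 10 at 8074935 to 8114934 (hg19) in parental MCF7 and its partner at 7886786 to 7926785, and the T47D partner anchor at 7883277 to 7923276. Both anchors sat in a domain from 7840001 to 8120000 that had the same ends in all 6 conditions. The INPP4B promoter anchor on chromosome 4 at 143752064 to 143792063 paired with an anchor starting at 143323700 in parental MCF7, and in T47D with one starting at 143325349. With sapitinib the partner anchor lay 73.9 kb away from the parental one in MCF7 and 74.9 kb away in T47D. By the read score of the authors' deposited tables GATA3 ranked 405 of 576 in parental MCF7 and 428 of 560 in parental T47D. With sapitinib it ranked 521 in MCF7 and 466 in T47D. INPP4B ranked 485 in parental MCF7 and 463 in parental T47D, and 558 and 507 with sapitinib.

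**Figure D4:**
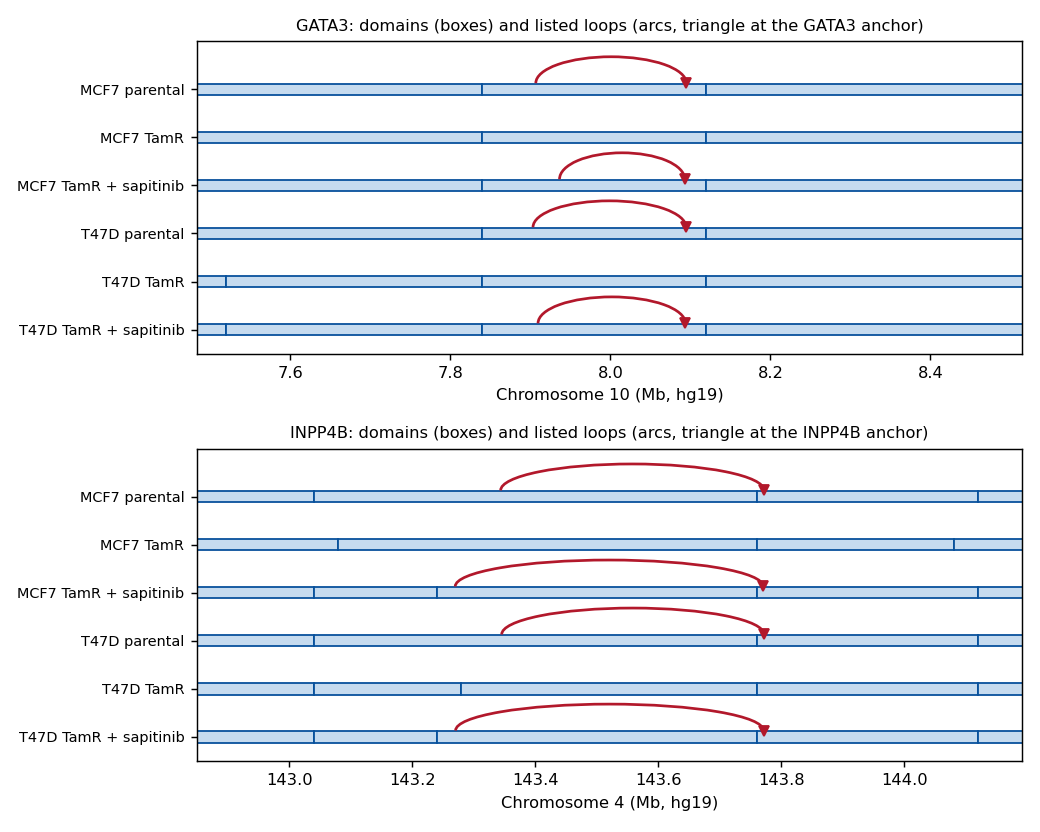
Boxes are domains and red arcs the listed loops, drawn between anchor centres along chromosome 10 and chromosome 4 (Mb, hg19), 1 row per condition. The resistant rows have no arc, and the box around GATA3 runs from 7840001 to 8120000 in each of the 6 rows.

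The other list genes differed by line. In MCF7, loops that were lost and came back also lay at INSR, the insulin receptor, at BIRC3, an inhibitor of apoptosis, and at the collagen gene COL1A2, a stromal marker. COL1A2 stood highest of these by the authors' parental read score, rank 21 of 576, but ranked 432 with sapitinib. Its partner anchor moved 372 kb. INSR and BIRC3 ranked 551 and 571 in parental cells, and 440 and 484 with sapitinib. MCF7 loops gained in resistance and lost with sapitinib lay at 7 list genes. They included CCND1 and CDK6, a cyclin and a kinase that together drive entry into the cell cycle, CREBBP, an acetyltransferase used by the estrogen receptor, and VIM, an intermediate filament of mesenchymal cells. The others were BID, a pro-apoptotic protein, GSTM1, a detoxifying enzyme, and CTCFL, a testis relative of CTCF. The CCND1 anchor on chromosome 11 at 69435991 to 69475990 paired with one starting at 69066580, a span of 369 kb, and ranked low in its list (494 of 527). In T47D, loops that were lost and came back also lay at BCL2, an anti-apoptotic protein, ELF3, an epithelial transcription factor, and NRG1, a ligand of HER3. The BCL2 loop spanned 294 kb on chromosome 18 and, by the read score of the authors' deposited table, ranked 56 of 560 in parental and 3 of 560 in sapitinib-treated cells. For NRG1 the returned loop used a promoter anchor 121 kb away and a partner anchor 1915 kb away from the parental ones. By the same read score NRG1 ranked 460 of 560 in parental cells and 560 of 560, the lowest of the list, with sapitinib. T47D loops gained in resistance and lost with sapitinib lay at SRC, a tyrosine kinase, at RARA, a retinoic acid receptor, and at SPRY4, a feedback inhibitor of MAPK signalling. SRC ranked 4 and RARA 16 of 192. ESR1, EGFR, ERBB2, ERBB3, PGR, GREB1, TFF1, MYC and CTCF named no loop of the 4 lists.

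The gene lists held too few genes with a loop for the tests of direction to decide. None of 28 two-sided Fisher's exact tests, of 14 lists in 2 lines against the other loop list of the line, passed Benjamini-Hochberg adjustment, 0 had an unadjusted p under 0.05 and the lowest was 0.228. A list had at most 2 genes with a loop in a line. That lowest p came from the MCF7 cell cycle list, whose 2 genes both had a gained loop. With so few genes none of the 28 tests could fall under 0.05, so they say nothing on direction. With all genes of the 4 lists as background, 0 of 56 tests had an unadjusted p under 0.05.

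The loops that scored most reads in the authors' deposited tables lay mainly at genes outside those lists. Shorter loops scored higher, and most of the first 10 of each list spanned less than 40 kb, so that their anchors overlapped. The leading loop spanned 37.2 kb and 67.5 kb in the lost and gained MCF7 lists, and 26.3 kb and 24.7 kb in the T47D ones. Lost loops were ranked by the parental score alone, and of the first 10, 6 in MCF7 and 3 in T47D were also among the first 10 by the score with sapitinib. In parental MCF7 these were RNF43, a ubiquitin ligase that restrains Wnt receptors, with 177 reads, then LINC02303, LINC01270, AKAP12, TNS4, SHISAL2B, YWHAB, SIAH3, SLC26A2 and LINC01727. The partner anchor of RNF43 moved by 1.63 kb between parental and sapitinib-treated cells, and that of SLC26A2, a sulfate transporter, by 209 kb. The gained loops of resistant MCF7 were led by the DNA helicase RECQL5 with 56.9 reads in the authors' deposited table, then FRMD6-AS2, SQLE, which makes squalene epoxide for cholesterol synthesis, MICOS10P1, TSHZ2, EFCAB3, LCAL1, PIPOX, COLGALT2 and C5orf64. In parental T47D the lost loops were led by the transporter gene SLC6A17 with 55.5 reads in the authors' deposited table, then LINC01727, CLEC9A, NAV1, SLC6A15, SPINT2, COL14A1, DCAF7, STAU1 and MAGI3. The gained loops of resistant T47D were led by ABHD17C with 88.6 reads in the authors' deposited table, then PCK1, a gluconeogenic enzyme, ECT2, a Rho exchange factor of dividing cells, SRC, PHOX2B, LINC00658, AQP9, HDAC7, MAT1A and KCNAB1. LINC01727 was among the first 10 of both lists of lost loops. The CTCFL loop gained in MCF7 and the PCK1 loop gained in T47D shared their anchors, on chromosome 20 at 56079006 and 56117235 in MCF7 and at 56078534 and 56116860 in T47D.

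The lines shared loops in every pair of lists. Of the MCF7 loops that were lost and came back, 60 had both anchors within 1 bin of such a T47D loop, against 2.14 by circular shifts, and of those gained and lost again 16 did, against 0.519 (both permutation p = 0.002, the smallest that 1000 shifts can give). Lists of opposite direction shared loops too, 12 against 0.792 and 26 against 1.60 (permutation p = 0.002). When the 2 T47D lists were mixed within chromosomes, an alternative chosen after seeing the data, no pair passed a permutation test of direction. The same-direction pairs shared 60 loops against 55.4 by chance and 16 against 12.2 (both adjusted permutation p = 0.226), and the opposite ones 12 against 18.8 and 26 against 31.2 (both adjusted p = 0.1998).

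In the 8 pairs of a loop list and a domain table, 55.4% to 72.6% of loops had at least 1 anchor in a changed domain, and none passed the circular-shift permutation test after adjustment (lowest adjusted p = 0.0959). With both anchors required, as set out before the data were examined, MCF7 loops that were lost and came back passed at both steps, with 69.1% against 61.0% by shifts in resistance and 59.0% against 52.3% with sapitinib (both adjusted permutation p = 0.0160). These shifts move anchors across domain borders. With the borders kept and the classes shifted along the domains, chosen after seeing the data, chance rose to 66.1% and 56.1% and neither passed (both adjusted permutation p = 0.396). Of the 18 list genes with a loop, 11 (61.1%) had their promoter anchor in a changed domain of both lines in resistance, against 52.0% of the 1689 other genes with a listed loop (p = 0.486, two-sided Fisher's exact test). They were COL1A2, INSR, CDK6, VIM, CREBBP, BID, ELF3, NRG1, BCL2, RARA and SRC. With sapitinib these were 4, INSR, CREBBP, BID and ELF3 (22.2% against 35.9%, p = 0.324, the same exact test), and GATA3, BIRC3, CTCFL, NRG1 and SPRY4 lay in domains unchanged in both lines.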

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

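The tests in this part were all chosen after the values were seen. One result stood out because the 2 lines moved in opposite directions. Of 5670 parental MCF7 domains, 32.3% were found with identical ends in resistant cells and 38.0% in resistant cells with sapitinib. Averaged over chromosomes this was 5.88 points more with sapitinib (SD 5.56, higher on 20 of 23 chromosomes, adjusted p = 1e-04, sign-flip permutation). Of 5683 parental T47D domains, 29.2% and 26.4% were found, a mean difference of -3.18 points (SD 4.35, higher on 7 of 23, adjusted permutation p = 9.4e-04). The lines differed by 9.07 points (permutation p = 1e-05, the smallest the resamples can give), and by 8.96 points when ends within 1 bin counted as found. In MCF7 the parental and sapitinib-treated cells have libraries in this series and the resistant cells do not. In T47D only the sapitinib-treated cells do. Libraries that resemble each other by origin could thus raise the MCF7 share and lower the T47D one, and the design does not separate this from sapitinib.

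A return of lost domains with sapitinib is 1 candidate explanation of the MCF7 part. In T47D, where the same MCF7 domains were also found more often with sapitinib than in resistance (33.0% against 28.6%, 4.92 points, adjusted permutation p = 1.6e-04), the gain was lower by 0.96 points (SD 7.77, adjusted permutation p = 0.561), so these data do not decide it. The 4.92 points are what would be seen if libraries of this series resembled each other or if the resistant T47D calls stood apart. T47D parental domains were found more often in sapitinib-treated than in resistant MCF7 (2.54 points, adjusted permutation p = 0.0121), as they would be if the resistant MCF7 calls stood apart. The MCF7 domains gained 3.34 points more there (adjusted permutation p = 0.0375), as they would with a return or with libraries that resemble each other.

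Parental domains missing in resistance do not help to decide, since they were chosen as absent from the resistant calls, with which the sapitinib-treated calls of a line share the most domains, and this lowers what is found there. Of these, 22.6% of 3836 were found with sapitinib in MCF7 and 11.7% of 4022 in T47D, against 21.04% to 25.6% and 19.97% to 25.6% in the conditions of the other line. Sapitinib-treated T47D calls that stand apart from all others are argued against as the whole cause by the 4.92 points, since parental MCF7 domains were found there more often than in resistant T47D. A difference between cultures or libraries remains open.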

How the results depend on the processing

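No paired analysis was possible because the tables hold comparisons and no columns per library. For the same reason there was no library to leave out in turn and no other grouping of libraries to try, and the depth behind the calls is unknown. Gene positions widened by a bin, gene bodies and the test of gene lists over changed domains were not run, since no hg19 annotation was used here. Of 232 alternatives to 33 results, 197 kept their direction and side of the threshold, or stayed within the interval of the main value or 1.5 times the main count. Counting only fusions, splits, shifts and losses, mixing the 2 T47D loop lists, shifting classes along the domains or permuting them within 5 classes of domain length, comparing both anchors with the other loop list, both alternatives for parental domains found and the count of 1 gene per promoter loop were chosen after seeing the data.

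The share of changed domains depended on what counted as change, for the 4 comparisons in the order MCF7 to resistance, MCF7 with sapitinib, T47D to resistance and T47D with sapitinib. By base pairs it was 72.7%, 62.0%, 75.1% and 61.6%. With ends within 1 bin as unchanged it was 42.8%, 31.9%, 48.0% and 34.8%, and within 2 bins 37.4%, 27.7%, 41.5% and 30.7%. With fusions, splits, shifts and losses alone it was 37.3%, 27.99%, 40.4% and 30.4%. By construction these settings count fewer domains as changed, and base pairs give weight to long domains. The difference between T47D and MCF7 in resistance, 2.32 points and short of the threshold, passed at 3.18 points with chromosomes weighted by domains, at 4.34 points with a tolerance of 1 bin and at 3.14 points without chromosome 17. The cause was not tested. With identical anchors required, 0 loops were shared between the lines in any of the 4 pairs of lists, since anchors are placed to the base in each condition. Within 5 bins 115 and 31 loops of the same direction and 31 and 66 of opposite direction were shared, more by construction. With the 2 T47D lists mixed, a null that keeps T47D loops and tests direction alone, the 4 pairs no longer passed. The same-direction pairs shared 60 loops with 55.4 by chance and 16 with 12.2, and the opposite pairs 12 with 18.8 and 26 with 31.2. The opposite pairs lay above the circular shifts but below the mixed lists, because the 2 nulls ask different questions. Their shortfall did not pass (both adjusted permutation p = 0.1998). With both anchors required in changed domains, MCF7 loops that were lost and came back passed at 69.1% in resistance (61.0% by shifts) and 59.0% with sapitinib (52.3%). With classes shifted along the domains, whose borders stay, chance rose to 66.1% and 56.1% and neither passed, nor did they against the other MCF7 list (63.8% and 53.7%, adjusted p = 0.156, Fisher's exact test). With classes permuted within length, fewer T47D loops than by chance had an anchor in changed domains in 2 pairs, 55.4% against 63.3% for lost loops with sapitinib and 69.8% against 78.4% for gained loops in resistance. The stricter part of each loop list gives the same odds ratio by construction.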

Other observations

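Apart from the planned odds ratios of recurrence and their values by matching and by domain length, the tests in this part were chosen after the values were seen. The lines had 148 genes with a listed loop in both, and 97 of these (65.5%) had the same direction. The odds ratio of sharing a direction was 2.66 (p = 0.0172, two-sided Fisher's exact test over genes), and 2.56 with 1 gene per promoter loop (p = 0.0182, the same test). Shared loops were tested with the T47D lists mixed within chromosomes, each pair of lists alone. The same-direction pairs lay above the mixed lists (60 against 55.4 and 16 against 12.2, both adjusted permutation p = 0.226). The opposite ones lay below them (12 against 18.8 and 26 against 31.2, both adjusted permutation p = 0.1998). None passed, but these lean the same way as the genes and do not speak against them. No joint test over loops was run, and a shared direction is not settled. Loops were lost and came back in both lines at 77 genes, and at 47 of these the partner anchor of the lines lay within 1 bin. Examples chosen after their values were seen are NFE2L2, the regulator of the oxidative stress response, TOX3, a breast cancer risk gene, the noncoding RNA gene MALAT1, the ferritin gene FTH1, and IFNGR1, a receptor chain for interferon gamma. Of these 5 only NFE2L2 had its partner anchor within 1 bin in both lines, and the others had different partner anchors. Loops were gained and lost again in both at 20 genes, among them WNT10A, a Wnt ligand, AQP9, DLX2, PHOX2B and SKAP1, with the partner anchor within 1 bin at 15 of the 20 (not at SKAP1). GATA3 and GATA3-AS1 share a promoter region, and U2AF1 and U2AF1L5 are near-identical copies, so such pairs are not independent.

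T47D loops gained in resistance and lost with sapitinib lay on chromosome 20 in 15 of 192 cases (7.81%), against 24 of 1663 loops of the other lists (1.44%, odds ratio 5.79, p = 2.6e-06, two-sided Fisher's exact test, chromosome chosen after seeing the counts). The 4 lists differed in their spread over chromosomes (p = 1e-04, the smallest that 10000 permutations can give). Gaps of the first condition that held a new domain numbered 210 from resistant to sapitinib-treated T47D, against 48, 54 and 61 in the other comparisons. Every gap was in this class, so the 210 count the gaps in the resistant T47D calls. Boundaries with a new domain numbered 67 there, against 102, 72 and 110 in the others.

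Chromosome 20 held 3 and 1 of the first 10 loops by read score in the lost and gained MCF7 lists, and 2 and 3 in the T47D lists, and 8 of all 576 lost MCF7 loops. Shorter loops score higher, but with the trend over span removed the lost MCF7 loops of chromosome 20 still lay 0.98 above the others on the log2 scale (adjusted p = 0.0074, permutation, over all chromosomes and lists), which argues against span as the whole cause. More copies of the chromosome may raise reads. The difference was 0.73 and 0.93 in the MCF7 gained and T47D lost loops (adjusted permutation p = 0.0417 and 0.0063) but 0.17 in the T47D gained loops (adjusted p = 0.554), and without copy numbers this stays open. Chromosome 8 scored 0.28 to 0.65 higher in the 4 lists and passed in 2 of them. Only chromosomes 19 and 22 passed in all 4 lists, both lower, by -0.54 to -0.99 and -0.55 to -0.90 (highest adjusted permutation p = 0.0381). The authors' read normalization is not stated, and no biological explanation was tested.

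Resistant domains that differed from parental ones also differed with sapitinib, with odds ratios of 5.26 in MCF7 and 2.92 in T47D. Looser matching lowered them, to 3.41 and 2.34 with ends within 1 bin and to 2.13 and 1.77 by 50% reciprocal overlap. Domain length does not account for this recurrence, since the lowest odds ratio within 3 classes of length was 4.92 in MCF7 and 2.57 in T47D. With the domains of a condition of the other line in place of the parental ones, the odds ratio was 3.77 to 5.54 in MCF7 and 3.57 to 4.65 in T47D. This is consistent with some resistant domains being called in no other condition, whether by chance of calling or because those boundaries are weak. With the other line's parental domains it was lower than with the own ones in MCF7 (3.77) and higher in T47D (4.62), so a response of the same regions at both steps stays open.

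A further hypothesis was that promoters with a loop gained in resistance lay with their partner inside 1 domain more often in resistant cells. In MCF7 this held for 79.9% of 527 loops with parental domains and 82.2% with resistant ones, a difference of 2.28 points (adjusted p = 0.351, exact McNemar test over loops), which leaves it open. In T47D it held for 77.6% and 83.3% of 192 loops, 5.73 points more (adjusted p = 0.173, the same exact test). None of 8 such tests passed adjustment. The lowest adjusted p was 0.101 in the exact McNemar test, for the fall of 3.61 points in the 527 MCF7 loops with sapitinib.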
